A study of Mus musculus with 2 samples.

How the data were processed

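RNA sequencing libraries were made from total RNA of cultured hepatocytes with a TruSeq RNA kit, per the labels. The cultures received 1 µM GW3965 or DMSO, and each group had 1 library. Per the submitters' processing notes the authors used CASAVA, TopHat2 2.0.6, Cufflinks 2.0.2 and Cuffdiff with the mouse builds mm9 and NCBIM37. Settings, strand handling and library scaling are not given in the sources used here.

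The deposited values are FPKM, fragment numbers scaled by the authors to transcript length and library size, and per the file headers there is one such column per library. The authors' table also gives a p-value and a q-value per gene, per the file headers. Its test statistic is a score made by the authors, whose sign is opposite to that of the fold. Calls in the authors' table were those with q of at most 0.0470, and the lowest q among genes not called was 0.0509. The standard error of a log2 fold was derived as the log2 ratio of the listed FPKM values over the score, both in size. FPKM values of genes with 1 or few reads are coarse, and FPKM of RNAs shorter than the fragments rest on very small effective lengths, so that few reads give high values.

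The table names its libraries DMSO and GL. GL was read as the GW3965 library, since the labels give 1 other sample, and that reading is not certain. Of 36808 genes, 7 carried the mark for too many fragments and were listed at 0 in GW3965. They were left out, and the 73 genes whose test failed were kept because they have FPKM values.

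Ratios were computed as log2((FPKM + 1) in GW3965 over (FPKM + 1) in DMSO). Genes with an FPKM of at least 1 in either library entered the counts, at a size threshold of 1.5-fold. With 1 library per group no p-value or SD was computed. Each of 27 gene lists was described by the median over its members at the minimum FPKM and by that median's percentile among 10000 random lists of the same size, drawn from 20 bins of mean expression. Members of a pathway vary together, which random lists do not reproduce. Of the 26 lists with members, 7 lay above and 9 below the central 95%.

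Before the data were examined, the lists, the thresholds and the rule for named genes were fixed. The rule takes the 12 highest and 12 lowest ratios, up to 4 members of each list with the largest ratios in size, a preset set of LXR and sterol genes, and genes within 500 kb of Abca1. Some genes the rule takes are not reported here. The preset symbol for LeXis matched no gene of the table. LeXis was instead identified as 4930412L05Rik, because Lexis1 of RefSeq covers 100% of the 4930412L05Rik span in the GRCm38 annotations and the table carries the same Ensembl identifier. Further members of the fixed lists and genes from the authors' calls were named after their values were seen.

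Gene classes came from GENCODE M21 by identifier, which matched 31833 of the 36808 genes. It is built on GRCm38, so positions are those of the table in mm9. GENCODE coordinates served only for gene and transcript lengths and for the overlap of 4930412L05Rik with Lexis1. Table starts were taken as counted from 0, since 58.5% of 19846 loci with 1 gene then had the GENCODE length, against 1.53% otherwise, and 1 was added. Several genes can share a locus. Shared sequence between genes was measured as the share of 25-base words of one gene's GENCODE transcripts found in those of another, on either strand. Long genes were protein-coding or long noncoding with a transcript of at least 300 bases.

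Depth was derived from low values. Among 3129 low genes above 0 in both libraries, the most frequent ratio of DMSO to GW3965 FPKM was 1.24, which is 1 read against 1 read. After division by it, 61.6% of the ratios lay within 0.1% of a ratio of whole numbers up to 10, against 1.21% when every ratio was moved by 3%. Genes with 1 annotated transcript gave the absolute scale, about 63600000 fragments for DMSO and 78400000 for GW3965. These are estimates, and intervals from them cover counting error only.

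Alternatives were another pseudocount, another minimum FPKM, a 2-fold threshold, centring on the median, scaling each library to the same sum, and use of the genes the authors tested. On simulated data for this comparison with 11796 genes, the size rule recovered 46 of 50 genes raised 2-fold, 42 of 50 lowered to 0.50 and 50 of 50 raised 3-fold, and 27 of 11596 unchanged genes passed. Of 100 simulated lists of 20 genes without a shift, 7 lay outside the central 95%, and 100 of 100 shifted by 0.3 lay above it. The simulated noise was of an assumed size, larger at low FPKM, and drawn separately for each gene. It held no difference between cultures and no genes that vary together. These counts check the rules and are not error rates of the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.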

Results

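Gene expression was measured by RNA sequencing in primary hepatocytes of C57Bl6 mice, that is, liver parenchymal cells isolated and kept in culture. The cells had received 1 µM GW3965, a synthetic agonist of the liver X receptors (LXR), or its solvent DMSO. LXRs are nuclear receptors that sense oxysterols and control genes of cholesterol efflux and fatty acid synthesis. There was 1 library per group, so no difference given here has a replicate check. The deposited table names its second library GL, which was read as the GW3965 library because the labels describe no other partner for DMSO. Whether those letters stand for an additional ligand cannot be told from the table.

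The table held 36808 genes, of which 11796 reached an FPKM of 1 in either library. The steps between low FPKM values placed the scale of the DMSO library at about 63600000 fragments and that of the GW3965 library at about 78400000. An FPKM of 1 on a transcript of 1000 effective bases then stood for about 63.6 and 78.4 fragments. The median log2 ratio of GW3965 to DMSO over those genes was 0.01, and 97.7% of them lay within 1.5-fold. Ratios are given as log2((FPKM + 1) in GW3965 over (FPKM + 1) in DMSO), a scale that understates differences of genes with low values.

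The comparison of GW3965 with DMSO asks which transcripts differ when LXR is activated in hepatocytes. Among protein-coding and long noncoding genes with an annotated transcript of at least 300 bases, called long genes here, the 5 highest ratios were those of Abca1, Scd1, Scd2, the cytochrome P450 gene Cyp1a2 and Abcg1. Abca1, which exports cholesterol to apolipoprotein A-I (ENSMUSG00000015243, chromosome 4, 53043659 to 53172767, mm9), had an FPKM of 14.6 in DMSO and 81.1 in GW3965, a log2 ratio of 2.40. Scd1, the stearoyl-CoA desaturase (ENSMUSG00000037071, chromosome 19, 44468941 to 44482199), had 206 and 980 (2.25), and its relative Scd2 had 9.16 and 42.8 (2.11). Abcg1, another sterol transporter, had 3.28 and 16.3 (2.01). At the other end, Hamp, which encodes the iron hormone hepcidin (ENSMUSG00000050440, chromosome 7, 31727390 to 31729036), had 186 and 67.9 (-1.44).

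In all, 120 genes were at least 1.5-fold higher and 157 at least 1.5-fold lower in the GW3965 library. Of these, 92 higher and 89 lower genes were long genes, a restriction chosen after the data were seen. Of all long genes at the minimum FPKM, 1.61% passed 1.5-fold, against 18.05% of the remaining genes, of which 259 had no annotated class and most others were pseudogenes or small RNAs. The 12 lowest ratios all belonged to genes outside that class and were listed at 0 in GW3965, for example Snord23 with 31.6 FPKM in DMSO. Among the 12 highest ratios, 9 belonged to genes outside it and 7 were listed at 0 in DMSO, with AL845466.1 at 627 FPKM and Gm3625, a protein-coding gene too short for the class, at 283 FPKM in GW3965. Alb and Trf, which encode albumin and transferrin, were listed at 7244 and 6727 FPKM in DMSO and at 0 in GW3965 with the table's mark for loci of too many fragments. Those zeros are failed estimates and were not used.

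**Figure D1:**
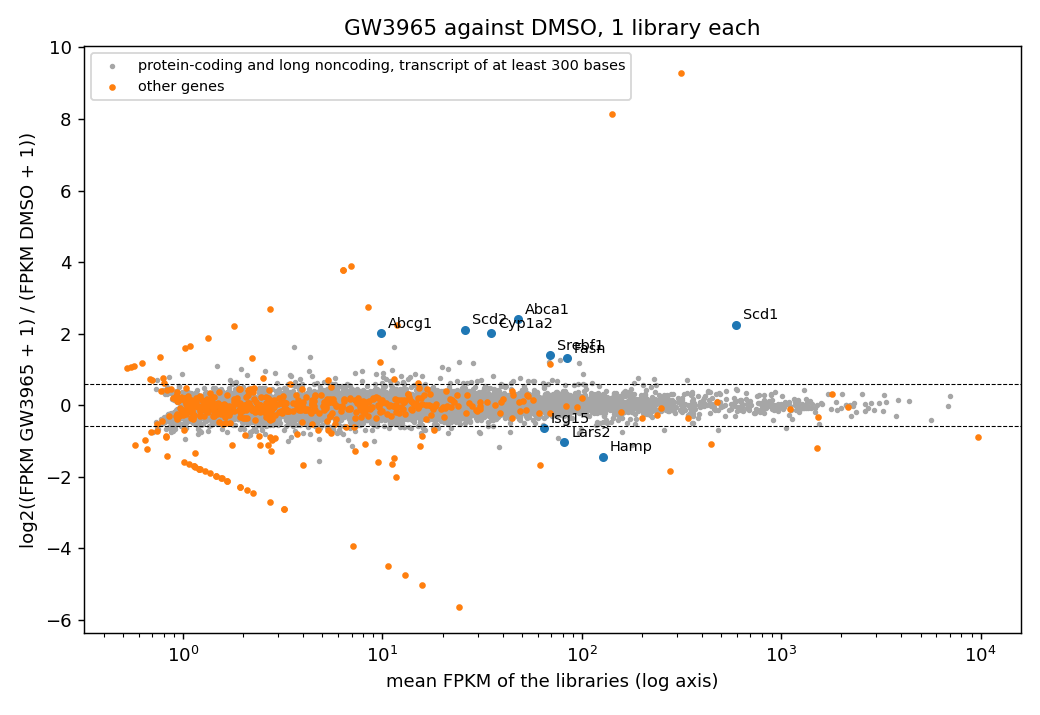
Log2 ratio of GW3965 to DMSO, each FPKM plus 1, against the mean FPKM of the libraries on a log axis, for the 11796 genes at an FPKM of at least 1 in either library. Grey points are protein-coding and long noncoding genes with a transcript of at least 300 bases, orange points are other genes, dashed lines mark 1.5-fold, and blue points are named genes such as Abca1 at 2.40 and Hamp at -1.44.

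LXR target genes were higher in the GW3965 library as a group. Of the 24 members of this list at the minimum FPKM, 11 were at least 1.5-fold higher and 0 at least 1.5-fold lower. Srebf1, which encodes the lipogenic transcription factor SREBP-1, had an FPKM of 37.6 in DMSO and 100 in GW3965 (1.39), Lpcat3, a phospholipid-remodelling acyltransferase, had 45.3 and 109 (1.25), and Mylip, a ubiquitin ligase, had 1.45 and 3.71 (0.95). Other members stood near or below 0, among them Apoe at -0.15, Nr1h3, which encodes LXRα, at -0.29, and Mlxipl at -0.17. Abcg5 and Abcg8, the canalicular sterol transporters, were below an FPKM of 1 in both libraries, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.00394 and 0.00634. The median log2 ratio of the list was 0.54, at percentile 100 of 10000 random lists of the same size and expression, which describes these libraries and not the conditions.

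Genes of fatty acid and triglyceride synthesis were also higher. Of 23 members, 9 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median of 0.56 at percentile 100. Fasn, the fatty acid synthase, had 47.7 FPKM in DMSO and 120 in GW3965 (1.31), Fads2, a fatty acid desaturase, had 58.4 and 135 (1.19), and Lpin1, a phosphatidate phosphatase, had 7.09 and 15.1 (0.99). Dgat2, which completes triglyceride synthesis, went the other way at -0.31. This list shared 4 measured members with the LXR target list, and without them its median was 0.43.

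All 19 measured genes of cholesterol synthesis were higher in the GW3965 library, by small amounts. Their median was 0.39, at percentile 100, and Pmvk at 0.71 alone passed 1.5-fold. Fdps, the farnesyl diphosphate synthase, stood at 0.58 and Sqle, the squalene epoxidase, at 0.23. Hmgcs1 was listed at 0 in both libraries and gives no value. Among 11 measured genes of the preset list on sterol uptake and SREBP-2 feedback, the median was 0.18, at percentile 99.9. Of these, Insig1 stood at 1.20 and Srebf2 itself at 0.18.

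Interferon response genes were lower in the GW3965 library. All 17 measured members had a ratio below 0, 3 of them by at least 1.5-fold, and the median was -0.43, at percentile 0. The authors' deposited table called 0 of these 17 genes. Ifit3 had 7.92 FPKM in DMSO and 4.36 in GW3965 (-0.74), Isg15 had 78.8 and 49.8 (-0.65), and Ifi44 had 13.3 and 8.22 (-0.63). Cell cycle genes were lower in 16 of 17 cases, with a median of -0.33 at percentile 0 and Top2a at -0.82 and Cdk1 at -0.69. Beside these lists, macrophage markers had a median of -0.15 at percentile 0.17, stellate cell and fibroblast markers 0.15 at percentile 99.9, and endothelial markers 0.10 at percentile 96.7.

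Inflammatory cytokines and NF-κB targets had a median of -0.18, at percentile 0, with Cxcl1, a neutrophil chemokine, at -0.75 and Mmp9 at 0.62. Acute phase genes had a median of -0.09, at percentile 0.37. Of 20 members 3 were at least 1.5-fold lower, namely Hamp and the fibrinogen chains Fga at -0.69 and Fgg at -0.68. Genes of PPARα and fatty acid oxidation had a median of -0.08, at percentile 0.915, with Vnn1 at -0.69 and Cpt1a, which carries fatty acids into mitochondria, at -0.65. Xenobiotic response genes had a median of 0.11, at percentile 99.4, led by Cyp1a2, a liver cytochrome P450, at 13.4 and 57.0 FPKM (2.01). ER stress genes stood at -0.10 (percentile 0.10) and immediate early and heat shock genes at -0.13 (percentile 0.19). The 6 measured members of the preset list of long noncoding RNAs stood at -0.19 (percentile 0.47). GENCODE classes 1 of these 6, Snhg11, as protein-coding. Oxysterol production and removal genes stood at 0.19 (percentile 99.5), and without Abca1 and Abcg1 at -0.02.

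Several groups lay within the range of random lists. Hepatocyte identity genes had a median of -0.01 at percentile 30.3, lipoprotein genes -0.03 at percentile 10.7, bile acid genes -0.05 at percentile 16.2, and gluconeogenesis genes -0.08 at percentile 7.25. Phospholipid remodelling genes stood at 0.05 (percentile 75.1), the LXR receptors and partners at 0.05 (percentile 69.0), housekeeping genes at 0.09 (percentile 94.2), and cholangiocyte markers at 0.05 (percentile 73.1). The 2 measured lymphoid and granulocyte markers stood at 0.03 (percentile 72.0), and 0 erythroid markers reached the minimum FPKM.

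**Figure D2:**
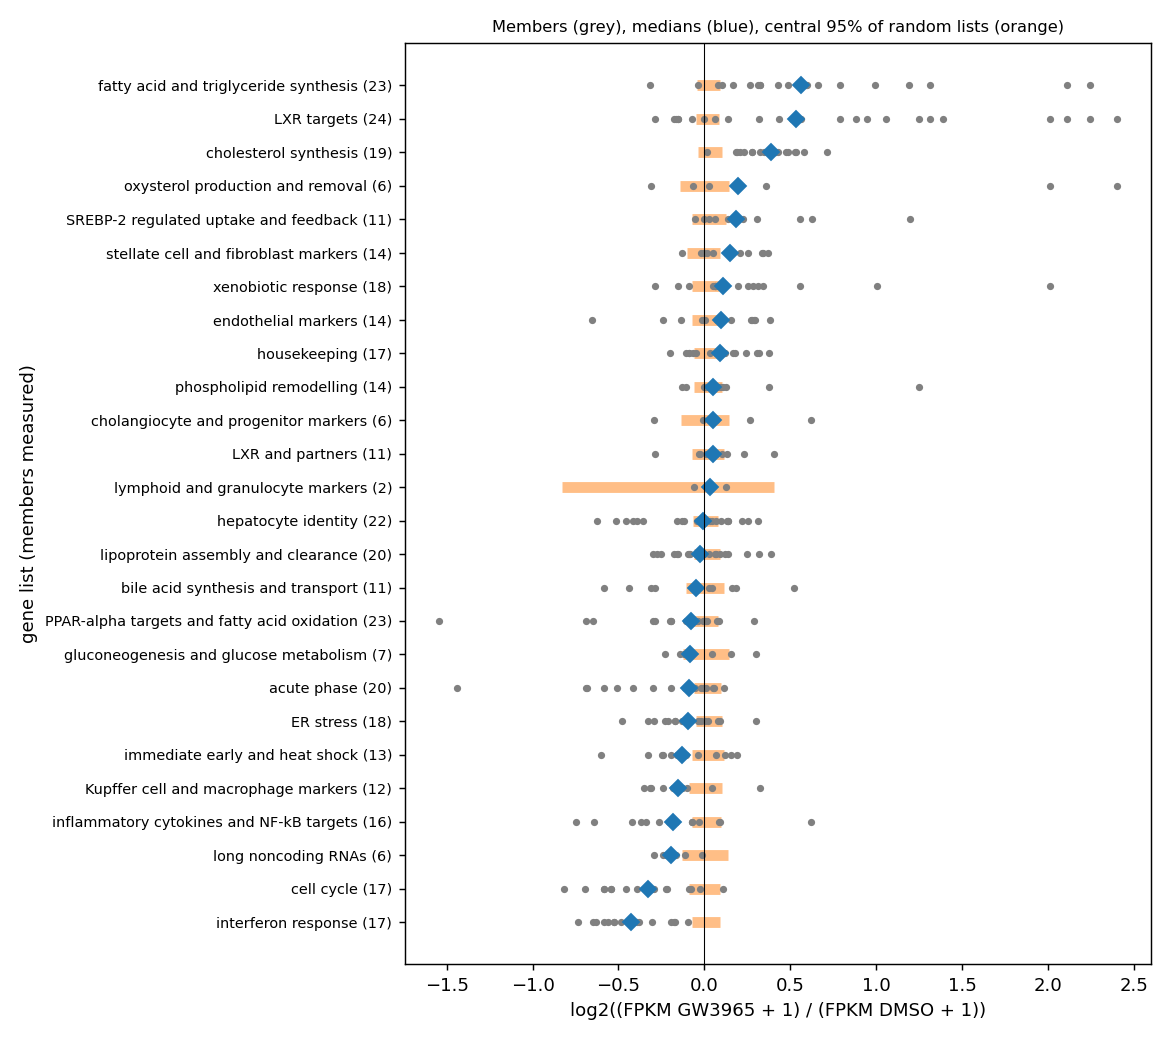
Log2 ratio of GW3965 to DMSO, each FPKM plus 1, for the measured members of each preset gene list (grey points, number in brackets), the list's median (blue diamonds) and the central 95% of medians of 10000 random lists matched on expression (orange bars). Fatty acid synthesis at 0.56 and LXR targets at 0.54 lie at the top, and interferon response at -0.43 at the bottom.

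The series is about LeXis, a noncoding RNA next to Abca1 that responds to lipids. LeXis corresponds to 4930412L05Rik (ENSMUSG00000087192, chromosome 4, 53217938 to 53230729, mm9). It lies at higher map positions than Abca1, with 45170 bases between the loci. Strand was not considered, so upstream and downstream of Abca1 are not told apart. The FPKM of 4930412L05Rik was 0.0146 in DMSO and 0.668 in GW3965, under the minimum of 1 used for the counts above, and its ratio with the pseudocount was 0.72. The steps between low values place these levels at about 1 read and 57 reads. The FPKM ratio was 45.9, with an exact 95% interval from counting of 7.91 to 1843, which leaves out any difference between cultures. For 4930412L05Rik the authors' deposited table gives p = 0.00330 and q = 0.397, without a call.

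Of the 23 genes within 500 kb of Abca1, 12 were listed at 0 in both libraries and 3 reached the minimum FPKM. Abca1 alone among those 3 passed 1.5-fold. Its neighbour Nipsnap3b had 35.4 FPKM in DMSO and 32.2 in GW3965 (-0.14), and Slc44a1, a choline transporter whose locus holds 1700060J05Rik as well, had 30.1 and 33.7 (0.16). Fsd1l, at 0.547 and 0.677, was under the minimum.

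**Figure D3:**
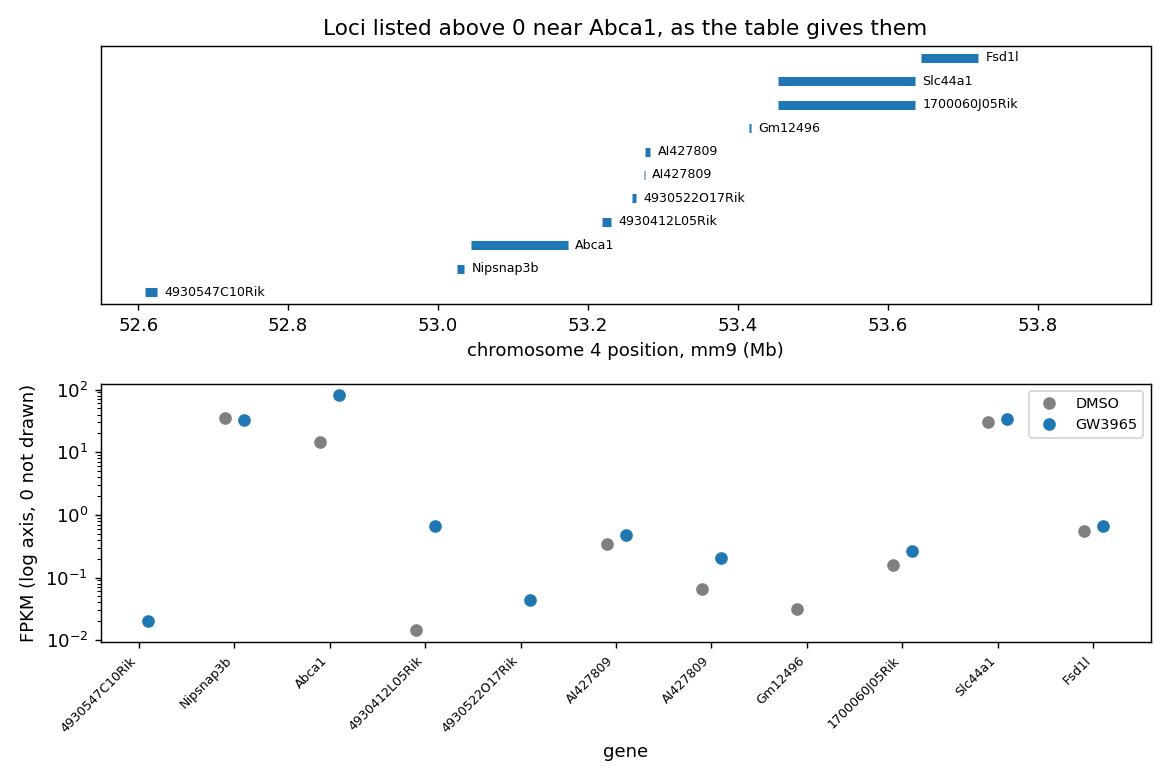
Top, position on chromosome 4 (mm9, in Mb) of the loci within 500 kb of Abca1 listed above 0. Bottom, their FPKM on a log axis in DMSO (grey) and GW3965 (blue), values of 0 not drawn. Abca1 goes from 14.6 to 81.1 and 4930412L05Rik from 0.0146 to 0.668, while Nipsnap3b stays at 35.4 and 32.2.

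The authors' deposited table calls 43 genes, 25 higher and 18 lower in the GW3965 library, with q of at most 0.0470. That test on the reads of 2 libraries compares those libraries, not the conditions. In the authors' deposited table Abca1 had q = 4.67e-06, Scd1 q = 1.71e-06, Insig1 q = 7.37e-08 and Hamp q = 9.67e-09. Sult1e1, the estrogen sulfotransferase, had q = 4.38e-09 in the authors' deposited table, with 5.03 FPKM in DMSO and 17.7 in GW3965. Srebf1 (q = 0.709), Fasn (q = 0.388) and Lpcat3 (q = 0.161) were not called in the authors' deposited table. The called pseudogene Gm8893 stays uncertain, because 80.7% of its 25-base words also occur in transcripts of the Serpina1 genes, with which reads can be shared.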

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

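The restriction to long genes (protein-coding or long noncoding, with a transcript of at least 300 bases) and the removal of shared list members were chosen after the data were seen. Counts past 1.5-fold moved by over 1.5 times with a pseudocount of 0.1 (194 higher, 320 lower) or 5 (56 and 56) and at 2-fold (39 and 55). The lower count was 82 at a minimum FPKM of 5 and 89 among long genes, since low and short genes drop out. Higher genes made up 43.3% of those past the threshold in the main setting, 37.7% with a pseudocount of 0.1, 39.7% after scaling to 1 sum, 40.4% after centring, 41.5% at 2-fold, 43.5% among genes the authors tested, 45.5% without a minimum, 50.8% among long genes and 51.5% at a minimum FPKM of 5. With a pseudocount of 5 the counts were equal, so the excess of lower genes depends on low and short genes. Counts of authors' calls, named genes and genes near Abca1 stayed within 1.5 times under every alternative run.

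List medians kept their direction wherever the list lay outside the central 95%, except oxysterol genes, at -0.017 without LXR targets, which removes Abca1 and Abcg1. With a pseudocount of 0.1 medians were 0.59 for LXR targets, -0.24 for inflammatory, -0.53 for interferon, -0.47 for cell cycle and 0.27 for oxysterol genes. With 5 they were 0.34, -0.10, -0.35, -0.19 and 0.090, and 0.43 for fatty acid synthesis and 0.076 for stellate markers. Without a minimum they were 0.38 for LXR targets, -0.11 for long noncoding RNAs and 0.0097 for oxysterol genes. At a minimum FPKM of 5 they were 0.47 for LXR targets, 0.036 for bile acid, -0.15 for PPARα, 0.26 for xenobiotic, -0.51 for interferon, 0.20 for stellate, -0.26 for cell cycle and 1.02 for oxysterol genes. Scaling to 1 sum gave -0.48 for interferon and -0.40 for cell cycle. Without shared members, LXR targets stood at 0.38 and fatty acid synthesis at 0.43. Pseudocounts, and the scaling through them, act by construction on low genes, and for the rest the cause was not tested. No paired analysis was possible because each group has 1 library. Depth limits genes under an FPKM of 1, LeXis among them.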

Other observations

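The genes of this paragraph were picked after their values were seen. Bdh1, the 3-hydroxybutyrate dehydrogenase, had 10.03 FPKM in DMSO and 3.97 in GW3965 (-1.15). The CXC chemokines Cxcl3 (-0.92) and Cxcl5 (-0.78) and the chemokine Ccl20 (-0.97) were lower, beside Cxcl1. Aldh1a1, which makes retinoic acid, had 244 and 112 FPKM (-1.12), and Rdh10, which makes its retinaldehyde substrate, had 25.5 and 45.8 (0.82). Gramd1b, a sterol transfer protein, had 1.25 and 5.93 (1.62).

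The genes of this paragraph were also picked after their values were seen. Of the listed genes, 7 of 14 of glucose metabolism and 11 of 18 of bile acid synthesis and transport had at least 1 FPKM in either library, among them Pklr at 86.0 in DMSO and Hsd3b7 at 30.4, and the others lay below. Among those below, G6pc was at 0.224 FPKM in DMSO and 0.0789 in GW3965, Pck1 at 0.123 and 0.0762, and Cyp8b1 at 0.0970 and 0.0993. Spp1 was at 4131 and 3373, Sprr1a at 3656 and 4040, and Vim at 432 and 547.

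Of the tests below, the one on Gm15564 was set before its value was seen, and all others after. Interferon and cell cycle genes were lower in the GW3965 library, with medians of -0.43 and -0.33. Macrophage markers were lower too, with a median of -0.15, but lay 0.27 above the interferon genes (95% bootstrap interval over genes 0.12 to 0.41). The interval treats genes as independent and leaves out any difference between cultures. Interferon genes were thus lower by more than the macrophage markers. Whether fewer macrophages contributed cannot be told, since interferon genes need not fall in proportion to the markers. Endothelial and stellate markers lay 0.47 above the cell cycle genes (0.30 to 0.69). The median of all genes was 0.011, which the authors' own scaling may have produced, so it does not test that scaling. After centring on that median, interferon genes stood at -0.44 and cell cycle genes at -0.34. Centring takes the same amount from every ratio, so these values follow by arithmetic and are no test. Apart from the pseudocount, a factor common to all genes of a library moves these lists and the other genes alike. A difference between the cultures other than the ligand cannot be told apart from an effect of GW3965, because there was 1 culture library per group.

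Srebf1, Fasn and Lpcat3 were at least 2-fold higher but not called in the authors' deposited table. Their standard errors, derived from the authors' deposited table, were 0.54, 0.45 and 0.38, while counting errors from reads estimated at their shortest annotated transcripts would be 0.074, 0.044 and 0.058, far below the standard error in all 3, so few reads do not account for them. This test replaces a comparison with genes of the same FPKM, whose outcome the choice of genes not called had nearly fixed. Genes with several annotated transcripts had standard errors 0.038 above those of genes with 1 (95% bootstrap interval 0.035 to 0.042). That met the bound written against the explanation, but a median over all genes does not bear on 3 genes of the tail. All 3 have several transcripts, as do 91.5% of the genes compared, so this does not favour the explanation either. Abca1 and Scd1, which were called, had standard errors of 0.42 and 0.37 with 2 and 3 annotated transcripts. Their log2 folds without the pseudocount were 2.48 and 2.25, against 1.42 for Srebf1, 1.33 for Fasn and 1.27 for Lpcat3. A wide error alone thus does not separate Lpcat3 from called genes, and its fold was smaller. The number of transcripts stays open as a source of the wide errors of Srebf1, Fasn and Lpcat3.

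Lars2, a mitochondrial leucyl-tRNA synthetase, had 109 FPKM in DMSO and 53.1 in GW3965. Its transcripts share 28 of 11142 words of 25 bases (0.25%) with those of Gm15564, so reads of a repeated sequence were a candidate explanation. Gm15564 was listed at 0 in DMSO and 0.0308 FPKM in GW3965, a log2 ratio of 0.044. That met the bound set in advance against the explanation, but the bound was a poor one, since a gene with almost no reads decides nothing, and the explanation stays open. Mitochondrial ribosomal RNA did not follow Lars2, with mt-Rnr2 at -0.078 and mt-Rnr1 at 0.086. No biological explanation was tested for Lars2.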
